A study of Homo sapiens with 9 samples.

How the data were processed

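The values are integer counts per gene for 60683 genes in each of 9 libraries, made by the submitters with featureCounts against GRCh38 and deposited as raw counts, per the submitters' processing notes. Those notes also name DESeq2 for the submitters' own comparison and give no version of either tool. The aligner, the annotation release, the strand setting and the treatment of reads with several alignments were not given in the sources used here. Per the labels' protocols, RNA was taken with TRIzol, and mRNA libraries were sequenced on an Illumina NovaSeq instrument.

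Counts were analysed in R 4.3.3. Genes were filtered with edgeR 4.0.16 (filterByExpr), which left 16159, and libraries were scaled by TMM factors between 0.944 and 1.05. Each gene was fitted with edgeR's robust quasi-likelihood model with 1 coefficient per group (biological coefficient of variation 0.224), and 3 contrasts were tested 2-sidedly: oxaliplatin against untreated, sorafenib against untreated, and oxaliplatin against sorafenib. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its absolute value over the square root of the F statistic. Levels are in CPM, computed by edgeR with the TMM factors, and errors beside them are standard deviations. Loci are GRCh38 coordinates.

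Gene lists, 42 in all, were written before the data were examined, and 39 had at least 5 tested members. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the libraries and with fry. For each list the members were also adjusted over the list alone. Lists of colorectal epithelial identity genes and of renal epithelial and renal carcinoma genes were added after the most changed genes had been looked at.

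The rule for named genes had 3 parts. The first took the 8 highest and 8 lowest log2 fold changes of each drug against untreated, and 5 and 5 between the drugs, among called protein-coding genes with a mean of at least 5 CPM. The second took up to 4 members with the smallest adjusted p in the list's direction and a mean of at least 1 CPM, for each called list and for the first 4 lists. The third named fixed genes of endoplasmic reticulum stress, senescence, platinum handling, RAF signalling and inositol phosphate metabolism. Of these the text gives those that best show each group, and it names the libraries whose omission ended a call.

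Alternatives tried were DESeq2 1.42.0, RLE factors, scaling by library size only, no filter on low counts, a filter at a mean of 1 CPM, fits of 2 groups only, the replicate number as a block, a 2-fold threshold, and leaving out each library in turn. After the data had been seen, a correction per library for GC content and transcript length (loess, span 0.5) and the omission of genes overlapping another gene on the same strand were added. The procedure was tested on simulated data, drawn around each gene's mean over the 9 libraries with its fitted dispersion, in which 50 genes at each of 4 sizes of change were raised or lowered in oxaliplatin. At 1.5, 2, 3 and 4-fold, 4, 22, 37 and 43 of them were called, and 9 of 115 calls were false.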

Results

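Messenger RNA was sequenced from human cells labelled HCT-15, a line derived from a colorectal adenocarcinoma, in 3 untreated libraries, 3 libraries of cells kept in oxaliplatin and 3 libraries of cells kept in sorafenib. Oxaliplatin is a platinum drug that binds DNA, and sorafenib inhibits RAF kinases and several receptor tyrosine kinases. Per the labels, oxaliplatin was given at 0.5 µM for 7 days and raised through 1, 2 and 4 µM between day 10 and day 30, after which the cells stayed in 4 µM. Sorafenib was applied in a similar way, with doses that the labels leave open. The series asks how inositol hexaphosphate acts together with chemotherapy on senescence driven by endoplasmic reticulum stress in colorectal cancer, and the libraries here compare the drug-adapted cells with untreated ones. The total counts were 17138210, 19181092 and 19780645 in the untreated libraries 1 to 3. They were 20936536, 17567589 and 15797076 in the oxaliplatin libraries and 18918545, 17489612 and 18837275 in the sorafenib libraries. Between 22564 and 24338 genes had at least 1 count in a library, and 16159 genes passed the filter on low counts.

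The 3 libraries of a group differed from each other by more than sampling noise, with chi-square values per degree of freedom between 18.7 and 40.4 over the 9 pairs, so each was counted as a separate sample. They carry 1 library code per group in their titles, and nothing states that they came from separate cultures. All p-values therefore measure only the spread between these libraries, which may be technical. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.970 to 0.979 for the 9 pairs within groups and 0.937 to 0.975 for the 27 pairs between groups. The first principal component held 36.6% of the variance and placed the oxaliplatin libraries at 34.6 to 52.4, above the untreated ones at -59.5 to -24.2. On it sorafenib 1 lay at -23.1, beside untreated 1 at -24.2, and sorafenib 2 and 3 lay at 10.3 and 4.25. Untreated 1 correlated with sorafenib 1 at 0.975 and with untreated 2 and 3 at 0.971 and 0.972. The second component held 17.8% and placed the sorafenib libraries at 31.8 to 38.8, with the untreated and oxaliplatin libraries at 1.21 or lower.

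Genes that mark colorectal epithelium were low or absent in all 9 libraries, and genes of renal epithelium were abundant. Of 20 colorectal identity genes, 14 had a median under 1 CPM, among them EPCAM (chr2:47345158-47387601), which encodes an epithelial adhesion molecule, with a median of 0.643 and a highest value of 1.38 CPM. CDX2, the intestinal homeobox factor (chr13:27960918-27969315), and CDH1, the gene of E-cadherin (chr16:68737292-68835541), had 0 counts in every library, as did CDX1, KRT20, PHGR1, HNF4A and CEACAM5. A count of 0 allows up to 3 counts, or 0.138 to 0.182 CPM depending on the library, and such floors cover counting error only. The keratin genes KRT8 and KRT18 had medians of 618 and 278 CPM, and ELF3 had 221 CPM. CLDN4 differed many-fold between libraries of the same group, with 164, 4.09 and 2.55 CPM in untreated 1 to 3, 62.7, 65.4 and 0.547 CPM in oxaliplatin 1 to 3 and 152 to 185 CPM in sorafenib. Of 22 genes of renal epithelium and renal carcinoma, 11 had a median of 10 CPM or more. PAX8, a transcription factor of the kidney and thyroid lineages (chr2:113215997-113278921), stood at 294 ± 49.6 CPM in untreated, 306 ± 25.8 CPM in oxaliplatin and 395 ± 14.8 CPM in sorafenib libraries (mean ± SD, n = 3 each). HAVCR1 and the organic anion carrier SLC17A3 had medians of 173 and 65.8 CPM, while CA9, NDUFA4L2 and EMX2 of the same list had medians under 1 CPM. Both lists were drawn up after the most changed genes had been seen, and the levels are given here because they bear on what the label HCT-15 covers. Of the markers of other cell types, 18 of 20 immune and 14 of 16 fibroblast and endothelial genes had a median under 1 CPM. Of 26 markers of liver, kidney, neural and other epithelial lines 19 did, and 6 had a median of 10 CPM or more. These 6 were PAX8, PAX2, the liver markers FGB and SERPINA1, at 102 and 20.7 CPM, and the neural markers NEFL and TUBB3, at 126 and 67.3 CPM.

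**Figure D1:**
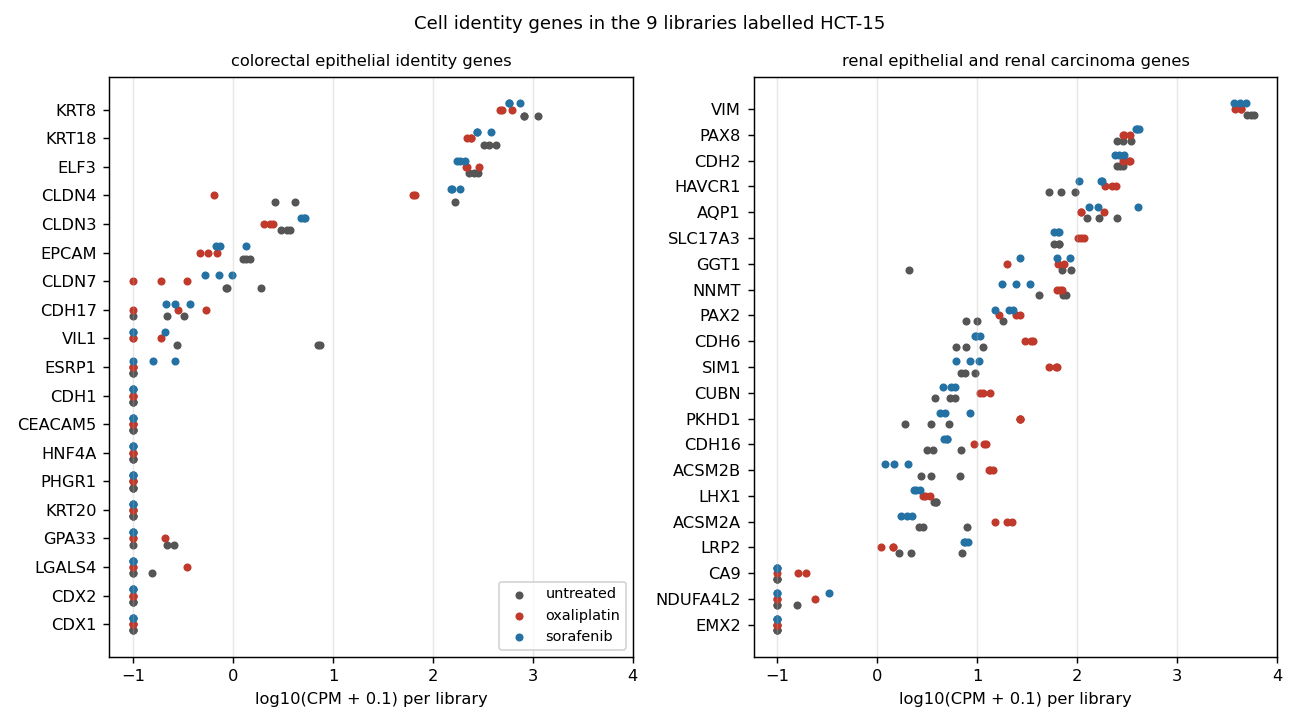
Points give log10(CPM + 0.1) of 19 of the 20 colorectal identity genes (left) and 21 of the 22 renal genes (right) in each of the 9 libraries, coloured by group. CDX2 and CDH1 lie at the bottom of the scale with 0 counts in all libraries, while PAX8 lies at 247 CPM or higher in each.

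The first comparison asks what differs in cells adapted to oxaliplatin. FN1, the gene of the matrix protein fibronectin (ENSG00000115414, chr2:215360440-215436073), rose from 10.3 ± 2.30 to 209 ± 4.21 CPM (mean ± SD, n = 3 each), a log2 fold change of 4.34 ± 0.17 (SE, adjusted p = 3.3e-06). As for every gene below, this is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CRISPLD2, which encodes a secreted protein (ENSG00000103196, chr16:84819985-84920768), rose from 6.01 ± 0.722 to 62.3 ± 1.91 CPM (log2 fold change 3.37 ± 0.16, adjusted p = 9.84e-06). Among the 8 lowest fold changes were ANKRD1, a target of the YAP coactivator (chr10:90912096-90921276), at -2.42 ± 0.39, SNORC at -2.12 ± 0.24, the ETS factor gene ETV4 (ENSG00000175832, chr17:43527844-43579620) at 1.01 ± 0.289 against 4.01 ± 0.438 CPM and the matricellular gene CCN5 (chr20:44714844-44728509) at -1.91 ± 0.25, with adjusted p-values of 0.00303, 0.00114, 0.00118 and 0.00167. SNORC overlaps GIGYF2 on the same strand, so the origin of its counts is uncertain.

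Of the 16159 genes tested, 5123 were called at an adjusted p under 0.05, 2619 higher and 2504 lower in oxaliplatin, which is 31.7%. With a change of at least 2-fold there were 1512, 1026 higher and 486 lower. The 3 oxaliplatin values lay all above or all below the 3 untreated ones for 48.1% of tested genes, where chance gives 10%. The number of calls fell to 2945 without untreated 2, 3293 without untreated 3, 2913 without oxaliplatin 1 and 3311 without oxaliplatin 2. Among the 8 highest fold changes, AC244197.3 (5.32 ± 1.59), ZBTB38 (3.79 ± 1.04), GPRIN3 (3.74 ± 0.93), CHP1 (3.17 ± 0.78) and AP001931.2 (2.99 ± 0.89) were uneven within groups, as was RAB43 (15.3 ± 19.6 against 1.90 ± 0.208 CPM), whose exons overlap ISY1-RAB43 on the same strand. Their adjusted p-values were 0.0192 to 0.0396. Without untreated 1, 4 of these 6 calls ended (adjusted p from 0.0779 to 0.0961), without untreated 2 all 6 (0.0748 to 0.131) and, without untreated 3, 4 of them (0.0694 to 0.114). Without oxaliplatin 1, 2 and 3, 5, 4 and 2 calls ended (0.0541 to 0.112, 0.0532 to 0.0694 and 0.0611 to 0.0834). The call of RAB43 also ended without sorafenib 1, 2 or 3 (adjusted p = 0.0556, 0.0621 and 0.0617) and that of AP001931.2 without sorafenib 3 (adjusted p = 0.0571). Over 17 alternatives the adjusted p of these 6 genes ran from 4.18e-06 to 0.131. RPS10-NUDT3 (-4.41 ± 1.24, adjusted p = 0.0311), a readthrough of 2 overlapping genes, and CGB5 (-1.99 ± 0.53, adjusted p = 0.0250) and CGB8 (-1.95 ± 0.47, adjusted p = 0.0165), near-identical copies of the chorionic gonadotropin beta gene, are uncertain for the way reads are shared. Their calls ended without untreated 1 (RPS10-NUDT3, adjusted p = 0.0528), untreated 2 (CGB5 and CGB8, up to 0.0843), untreated 3 (all 3, 0.0509 to 0.0859), oxaliplatin 1 (all 3, up to 0.120), oxaliplatin 2 (all 3, up to 0.0973) and oxaliplatin 3 (RPS10-NUDT3, 0.0872), with adjusted p-values from 1.69e-05 to 0.120 over 17 alternatives.

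Genes of cell proliferation fell together in oxaliplatin. In the list of DNA replication genes and E2F targets, 34 of 47 tested members fell and 0 rose (34 and 0 adjusted over the list alone). The median log2 fold change was -0.59 (limma's camera test, adjusted p = 4.31e-16; adjusted p = 0.307 with an estimated correlation). GINS2, a subunit of the replicative helicase (ENSG00000131153, chr16:85676198-85690073), fell by 1.49 ± 0.15 on the log2 scale, and MCM5, another helicase subunit (ENSG00000100297, chr22:35400134-35425431), fell from 225 ± 26.2 to 92.3 ± 9.72 CPM, each with an adjusted p of 0.000822. The sliding clamp gene PCNA had a log2 fold change of -0.94 ± 0.10 and the thymidine kinase gene TK1 of -1.18 ± 0.13 (adjusted p = 0.00106 and 0.00114). In the list of G2-M and mitosis genes 27 of 50 fell and 1 rose (30 and 2 adjusted over the list alone). The median was -0.43 (adjusted p = 1.12e-07; adjusted p = 0.458 with an estimated correlation). MYBL2, a transcription factor of proliferating cells, fell from 402 ± 55.6 to 160.4 ± 22.8 CPM, and the mitotic kinase gene PLK1 from 118 ± 3.08 to 70.5 ± 4.69 CPM. LMNB1, whose lamin B1 is lost in senescent cells (ENSG00000113368, chr5:126776623-126837020), had a log2 fold change of -0.74 ± 0.11 (adjusted p = 0.00203), while the proliferation marker MKI67 was at 0.08 ± 0.46 (adjusted p = 0.907).

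Of the 30 tested p53 targets, 10 rose and 3 fell (11 and 4 adjusted over the list alone). The median was 0.25 (adjusted p = 0.0293; adjusted p = 0.298 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.000478). The call also ended without untreated 1 (adjusted p = 0.0537) and without sorafenib 1 (adjusted p = 0.0576). CDKN1A, the gene of the cyclin-dependent kinase inhibitor p21 (ENSG00000124762, chr6:36676460-36687337), rose from 67.7 ± 9.40 to 199 ± 75.0 CPM (log2 fold change 1.56 ± 0.26, adjusted p = 0.00405). The death receptor gene EDA2R had a log2 fold change of 1.47 ± 0.18, the ribonucleotide reductase gene RRM2B of 1.01 ± 0.14 and the translesion polymerase gene POLH of 0.94 ± 0.11 (adjusted p = 0.00127, 0.00196 and 0.00118). In the list of cyclin-dependent kinase inhibitors and growth arrest genes 6 of 21 rose and 4 fell (6 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.547). Its members BTG2, an antiproliferative gene, and RBL2, a relative of the retinoblastoma gene, rose by 1.14 ± 0.16 and 0.87 ± 0.13. CDKN2A was at 0.59 ± 0.29 (adjusted p = 0.141) and the lysosomal galactosidase gene GLB1 at 0.24 ± 0.16 (adjusted p = 0.275). Of the 26 senescence-associated secreted factors 4 rose and 5 fell (4 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.989). INHBA, which encodes an activin subunit, rose by 1.04 ± 0.14 and VEGFA by 0.72 ± 0.15 on the log2 scale.

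Genes of the PERK-ATF4 branch of the stress response of the endoplasmic reticulum stood lower in oxaliplatin. Of 35 tested targets 15 fell and 2 rose (16 and 2 adjusted over the list alone). The median was -0.44 (adjusted p = 3.19e-05; adjusted p = 0.602 with an estimated correlation). ATF4 itself (ENSG00000128272, chr22:39519695-39522685) fell from 1062 ± 126 to 653 ± 64.9 CPM (log2 fold change -0.70 ± 0.13, adjusted p = 0.00488). TRIB3, a pseudokinase gene induced by ATF4 (ENSG00000101255, chr20:362835-397559), had -0.95 ± 0.19, the phosphatase subunit gene PPP1R15A -1.25 ± 0.21 and the amino acid transporter gene SLC7A5 -1.19 ± 0.14 (adjusted p = 0.00632, 0.0037 and 0.00118). DDIT3, which encodes CHOP, was at -0.51 ± 0.23 (adjusted p = 0.111). Of 42 chaperones and ATF6-XBP1 targets 11 fell and 5 rose (11 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.320). HSPA5, the gene of the chaperone BiP (ENSG00000044574, chr9:125234853-125241343), fell from 1193 ± 235 to 743 ± 26.4 CPM (log2 fold change -0.68 ± 0.14, adjusted p = 0.00713), MANF had -0.85 ± 0.13 and DNAJB11 -0.68 ± 0.13, while XBP1 was at 0.16 ± 0.16 (adjusted p = 0.469).

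Interferon-stimulated genes rose: 19 of 32 tested members were higher and 2 lower (22 and 2 adjusted over the list alone). The median was 0.70 (adjusted p = 1.81e-07; adjusted p = 0.269 with an estimated correlation). The guanylate-binding protein gene GBP1 (ENSG00000117228, chr1:89052319-89065230) rose from 2.30 ± 0.444 to 12.3 ± 0.689 CPM (log2 fold change 2.41 ± 0.31, adjusted p = 0.00158). The RNA sensor gene IFIH1 had 1.58 ± 0.21 (adjusted p = 0.00161). Genes of the epithelial-mesenchymal transition list rose, with 8 of 29 higher and 1 lower (9 and 1 adjusted over the list alone). The median was 0.22 (adjusted p = 0.00164; adjusted p = 0.269 with an estimated correlation). Besides FN1 these included THBS1, the gene of thrombospondin 1 (ENSG00000137801, chr15:39581079-39599466), from 302 ± 45.8 to 771 ± 48.1 CPM, the smooth muscle actin gene ACTA2 at 1.74 ± 0.26 and the integrin gene ITGB3 at 1.31 ± 0.17 (adjusted p = 0.000822, 0.00225 and 0.00151).

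Energy metabolism and ribosomal genes fell in oxaliplatin. The share of counts from mitochondrially encoded genes was 8.44 to 9.94% in untreated and 9.56 to 11.9% in oxaliplatin libraries, and that from ribosomal protein genes 6.24 to 7.11% and 4.87 to 5.23%. Of 46 nuclear-encoded genes of the respiratory chain 37 fell and 0 rose (40 and 0 adjusted over the list alone). The median was -0.69 (adjusted p = 1.23e-14; adjusted p = 0.458 with an estimated correlation). The cytochrome oxidase genes COX6C and COX8A had -0.97 ± 0.14 and -1.05 ± 0.16. Mitochondrially encoded mRNAs were not called as a list (3 of 13 rose, 2 adjusted over the list alone, adjusted p = 0.175). Of 70 cytosolic ribosomal protein genes 40 fell and 0 rose (47 and 0 adjusted over the list alone). The median was -0.53 (adjusted p = 2.74e-11; adjusted p = 0.602 with an estimated correlation). Of 19 glycolysis enzymes 10 fell and 0 rose (10 and 0 adjusted over the list alone). The median was -0.37 (adjusted p = 0.00126; adjusted p = 0.602 with an estimated correlation). GAPDH went from 6972 ± 1246 to 4153 ± 276 CPM (log2 fold change -0.75 ± 0.14, adjusted p = 0.00533). ABC drug efflux transporters rose, with 7 of 13 higher and 0 lower (7 and 0 adjusted over the list alone). The median was 0.61 (adjusted p = 0.0129; adjusted p = 0.602 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.000997). The call also ended without untreated 3 (adjusted p = 0.0665). ABCC2, a transporter of platinum conjugates, rose from 148 ± 31.3 to 240.2 ± 18.4 CPM (adjusted p = 0.0105), and ABCC4 and ABCC5 had 0.70 ± 0.14 and 0.74 ± 0.14, while ABCB1 was at 0.19 ± 0.21 (adjusted p = 0.512).

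For platinum handling itself, ATP7A, a copper-transporting ATPase that can export platinum (ENSG00000165240, chrX:77910656-78050395), rose by 1.40 ± 0.16 on the log2 scale from 6.82 ± 0.735 CPM (adjusted p = 0.00114). ATP7A overlaps PGK1 on the same strand in the annotation. The copper uptake gene SLC31A1 was at -0.21 ± 0.09 (adjusted p = 0.105), ATP7B at 0.70 ± 0.27 (adjusted p = 0.0753) and the excision repair gene ERCC1 at -0.22 ± 0.13 (adjusted p = 0.210). In the list of platinum and copper transport 3 of 14 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.989). In that of nucleotide excision repair 5 of 29 rose and 5 fell (5 and 5 adjusted over the list alone, adjusted p = 0.489). Neither list was called, and in both the median was below 0 (-0.05 and -0.23) and the mean above it (0.02 and 0.0045). Of 27 inositol phosphate kinases and phosphatases 8 rose and 4 fell (8 and 4 adjusted over the list alone, adjusted p = 0.504). IPMK, an inositol polyphosphate kinase gene, was at 0.67 ± 0.16 (adjusted p = 0.0133) and the phosphatase gene MINPP1, whose product acts on inositol hexaphosphate, at 0.40 ± 0.12 (adjusted p = 0.0333), but with a correction for GC content and length chosen after the data were seen their adjusted p-values were 0.986 and 0.376. Without untreated 2 and without oxaliplatin 1 the adjusted p of IPMK was 0.0559 and 0.0568, and that of MINPP1 was 0.0647, 0.0671, 0.105, 0.112 and 0.0837 without untreated 1, 2 or 3 and oxaliplatin 1 or 2, within ranges of 0.00306 to 0.986 and 0.0115 to 0.376 over 17 alternatives. IPPK, the kinase gene for inositol hexaphosphate synthesis, was at -0.20 ± 0.14 (adjusted p = 0.304).

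**Figure D2:**
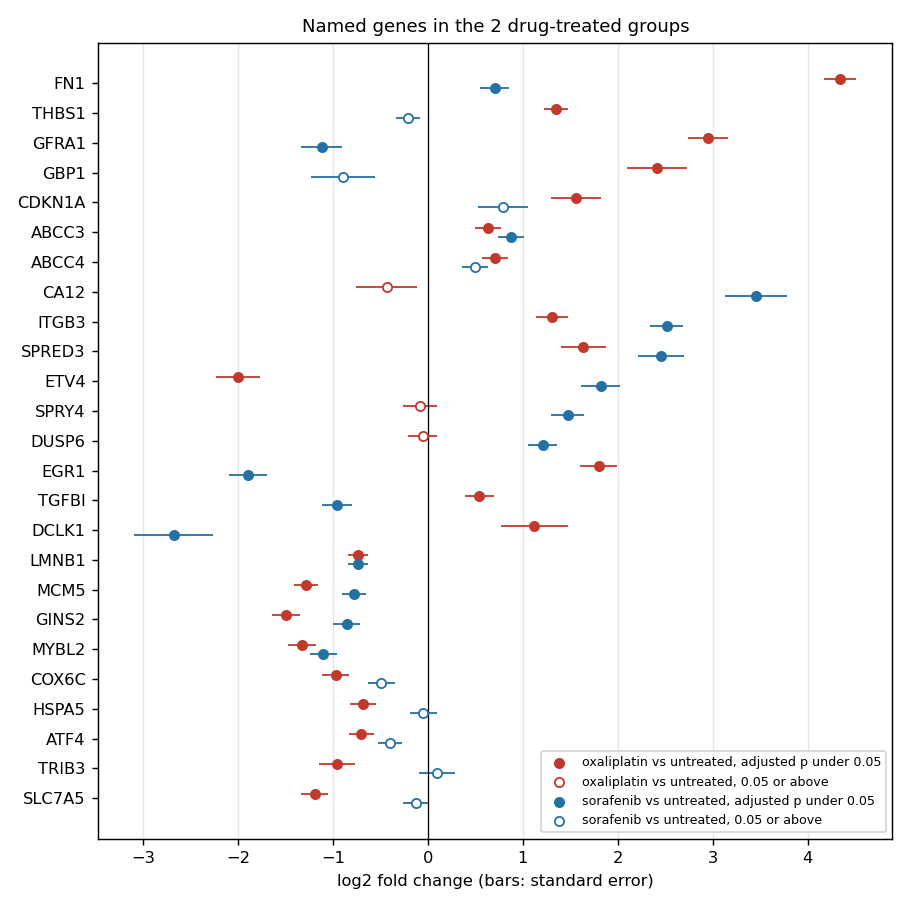
Points and error bars give the log2 fold change ± SE of 25 named genes against untreated libraries in oxaliplatin and in sorafenib (n = 3 per group), with filled points where the adjusted p was under 0.05. FN1 reached 4.34 in oxaliplatin and CA12 3.46 in sorafenib, and ETV4 was lower in oxaliplatin and reached 1.82 in sorafenib.

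The second comparison asks the same for sorafenib. CA12, the gene of carbonic anhydrase 12 (ENSG00000074410, chr15:63321378-63381846), rose from 5.39 ± 3.02 to 59.0 ± 4.49 CPM (mean ± SD, n = 3 each), a log2 fold change of 3.46 ± 0.33 (SE, adjusted p = 0.00171). ITGB3, an integrin gene (ENSG00000259207, chr17:47253827-47313743), rose from 6.97 ± 0.760 to 39.9 ± 6.89 CPM, and TMCC3 (ENSG00000057704, chr12:94567122-94650557) from 3.32 ± 0.337 to 18.1 ± 1.89 CPM, each with an adjusted p of 0.000191. SPRED3, a gene of an inhibitor of RAS-ERK signalling (ENSG00000188766, chr19:38388421-38399587), rose by 2.46 ± 0.24 on the log2 scale (adjusted p = 0.00171). AQP3, a water and glycerol channel gene (ENSG00000165272, chr9:33441156-33447596), fell from 22.1 ± 0.683 to 4.76 ± 0.413 CPM (log2 fold change -2.21 ± 0.14, adjusted p = 0.000137), and the prostaglandin-degrading enzyme gene HPGD (ENSG00000164120, chr4:174490175-174523154) from 19.2 ± 4.62 to 4.23 ± 0.760 CPM (-2.18 ± 0.22, adjusted p = 0.00173).

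In sorafenib 775 genes were called, 456 higher and 319 lower, which is 4.80% of those tested, and 314 with a change of at least 2-fold, 201 higher and 113 lower. Groups without overlap were found for 29.8% of tested genes, where chance gives 10%. The number of calls depended on single libraries: it was 1641 without untreated 1, 149 without untreated 2, 153 without untreated 3, 386 and 446 without oxaliplatin 1 and 2, and 1743, 139 and 113 without sorafenib 1, 2 and 3. The 2-fold count was 630, 112 and 114 without untreated 1, 2 and 3, and 493, 106 and 90 without sorafenib 1, 2 and 3. Of the other genes with the highest and lowest fold changes, HLF (3.06 ± 0.43), GRPEL2 (2.77 ± 0.62), HOXA3 (2.22 ± 0.42), RUNX2 (2.08 ± 0.49), the collagen gene COL1A1 (-4.22 ± 0.71), CGB3 (-3.59 ± 0.74), TAGLN (-2.98 ± 0.48), DCLK1 (-2.68 ± 0.42) and CGB5 (-2.61 ± 0.54) had adjusted p-values from 0.0105 to 0.0482. Some of these 9 calls ended without untreated 1 (adjusted p of 0.0599 and 0.0745), untreated 2 (0.0521 to 0.181), untreated 3 (0.0522 to 0.153), oxaliplatin 1 (0.0676 to 0.0800), oxaliplatin 2 (0.0648 to 0.0768), oxaliplatin 3 (0.0502 to 0.0675), sorafenib 1 (0.0522 to 0.0610), sorafenib 2 (0.0612 to 0.167) or sorafenib 3 (0.0511 to 0.154). Over 17 alternatives their adjusted p-values ran from 1.55e-12 to 0.181.

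Genes of ERK pathway output rose in sorafenib, with 8 of 31 higher and 2 lower (15 and 3 adjusted over the list alone). The median was 0.36 (adjusted p = 1.19e-05; adjusted p = 0.131 with an estimated correlation). ETV4 rose from 4.01 ± 0.438 to 14.2 ± 0.999 CPM (log2 fold change 1.82 ± 0.20, adjusted p = 0.00215). SPRY4, a feedback inhibitor gene of the pathway, had 1.47 ± 0.17 and DUSP6, the gene of an ERK phosphatase (ENSG00000139318, chr12:89347235-89352501), went from 9.34 ± 0.755 to 21.6 ± 3.29 CPM (1.21 ± 0.15, adjusted p = 0.00434). Among the 2 lower members was EGR1, which fell from 24.7 ± 5.24 to 6.64 ± 1.05 CPM (log2 fold change -1.90, adjusted p = 0.00191). Of the drug's targets, BRAF was at -0.25 ± 0.34 (adjusted p = 0.689). The list of target kinases was not called (1 of 6 fell, 1 rose and 1 fell adjusted over the list alone, adjusted p = 0.466). Receptor tyrosine kinases and their ligands rose, with 4 of 26 higher and 0 lower (8 and 3 adjusted over the list alone). The median was 0.27 (adjusted p = 0.0223; adjusted p = 0.299 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.00347). Without untreated 1 the list had an adjusted p of 0.0570. MET and EGFR, receptor genes of this list, both had 0.67 (SE 0.12 and 0.13, adjusted p = 0.0174 and 0.0273), with adjusted p-values of 0.0797 and 0.110 without untreated 2, 0.0724 and 0.0770 without untreated 3, 0.0759 and 0.106 without sorafenib 2, and 0.0851 and 0.111 without sorafenib 3. The lowest of their 17 alternatives were 8.28e-05 and 0.000737.

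Hypoxia targets rose as a list, with 6 of 28 higher and 0 lower (6 and 1 adjusted over the list alone). The median was 0.15 (adjusted p = 0.0117; adjusted p = 0.145 with an estimated correlation). Besides CA12 these included BHLHE41, a circadian repressor gene, at 2.39 ± 0.26 and NDRG1 from 196 ± 12.6 to 350.2 ± 29.3 CPM (adjusted p = 0.00191 and 0.00568). Heat shock genes fell, with 5 of 24 lower and 1 higher (12 and 1 adjusted over the list alone). The median was -0.33 (adjusted p = 2.65e-05; adjusted p = 0.131 with an estimated correlation). TGF-beta and SMAD targets fell, with 4 of 27 lower and 0 higher (5 and 2 adjusted over the list alone). The median was -0.21 (adjusted p = 0.0339; adjusted p = 0.299 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.0195). The call ended without untreated 3 (adjusted p = 0.0626) and without sorafenib 1 (adjusted p = 0.167). BAMBI, a decoy receptor gene of that pathway, fell from 27.4 ± 6.11 to 9.92 ± 0.898 CPM (log2 fold change -1.47 ± 0.18, adjusted p = 0.00389).

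Proliferation genes fell in sorafenib as well. In the list of DNA replication genes and E2F targets 16 of 47 fell and 0 rose (27 and 0 adjusted over the list alone). The median was -0.40 (adjusted p = 1.80e-14; adjusted p = 0.295 with an estimated correlation). TK1 went from 207 ± 22.6 to 106 ± 16.6 CPM (adjusted p = 0.00604). In the G2-M and mitosis list 7 of 50 fell and 0 rose (19 and 0 adjusted over the list alone). The median was -0.29 (adjusted p = 2.26e-07; adjusted p = 0.349 with an estimated correlation). MYBL2 had -1.10 ± 0.14 and LMNB1 -0.74 ± 0.11 (adjusted p = 0.00476 and 0.00748). Of 30 p53 targets 4 rose and 1 fell (9 and 1 adjusted over the list alone). The median was 0.24 (adjusted p = 0.00988; adjusted p = 0.145 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.00131). The call ended without sorafenib 1 (adjusted p = 0.0817). CDKN1A was at 117 ± 10.4 CPM against 67.7 ± 9.40 CPM in untreated libraries (0.79 ± 0.26, adjusted p = 0.102). Of 21 cyclin-dependent kinase inhibitors and growth arrest genes edgeR called 0 over all genes, with 7 higher and 3 lower at an unadjusted p under 0.05, while DESeq2 called 3 higher and 2 lower. Adjusted over the list alone 5 were higher and 2 lower, and the list was not called (adjusted p = 0.375). Of 26 senescence-associated secreted factors 2 rose and 0 fell (5 and 1 adjusted over the list alone), and that list was not called either (adjusted p = 0.989). ABC drug efflux transporters rose, with 4 of 13 higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.37 (adjusted p = 0.00801; adjusted p = 0.515 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.000352). The call ended without untreated 3 (adjusted p = 0.0703) and with fry, which tests for a movement one way on balance (adjusted p = 0.0531). ABCA3, a lipid transporter gene, went from 33.1 ± 0.383 to 67.5 ± 2.00 CPM (1.03 ± 0.10, adjusted p = 0.00147).

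Most genes of endoplasmic reticulum stress did not pass the test in sorafenib. HSPA5 stood at 1153 ± 44.9 CPM against 1193 ± 235 CPM (log2 fold change -0.05 ± 0.14, adjusted p = 0.864), TRIB3 at 0.10 ± 0.19 (adjusted p = 0.785), DDIT3 at -0.19 ± 0.23 (adjusted p = 0.640) and ATF4 at -0.40 ± 0.13 (adjusted p = 0.0974). Of 42 chaperones and ATF6-XBP1 targets 1 rose and 0 fell (3 and 2 adjusted over the list alone), and the list, with a median of -0.01 and a mean of 0.03, was not called (adjusted p = 0.861). PERK-ATF4 targets had 1 of 35 lower and 0 higher (1 and 0 adjusted over the list alone). The median was -0.19 (adjusted p = 0.0223; adjusted p = 0.655 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.000232). That call ended without untreated 2 (adjusted p = 0.231) and without untreated 3 (adjusted p = 0.0930). The respiratory chain and ribosomal protein lists were called lower, with medians of -0.34 and -0.27 (adjusted p = 4.59e-07 for each; adjusted p = 0.521 with an estimated correlation for each), although edgeR called 0 of 46 and 0 of 70 members, over all genes and adjusted over the list alone. At an unadjusted p under 0.05, 17 members of each list were lower and 1 and 0 higher, and DESeq2 called 8 and 3 lower. The share of counts from ribosomal protein genes was 6.64% in sorafenib 1, within the untreated range of 6.24 to 7.11%, and 5.21% or lower in sorafenib 2 and 3. The fry test, which asks whether the genes of a list move one way on balance, gave adjusted p-values of 0.0851 and 0.121, and of 0.264 for PERK-ATF4 targets.

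**Figure D3:**
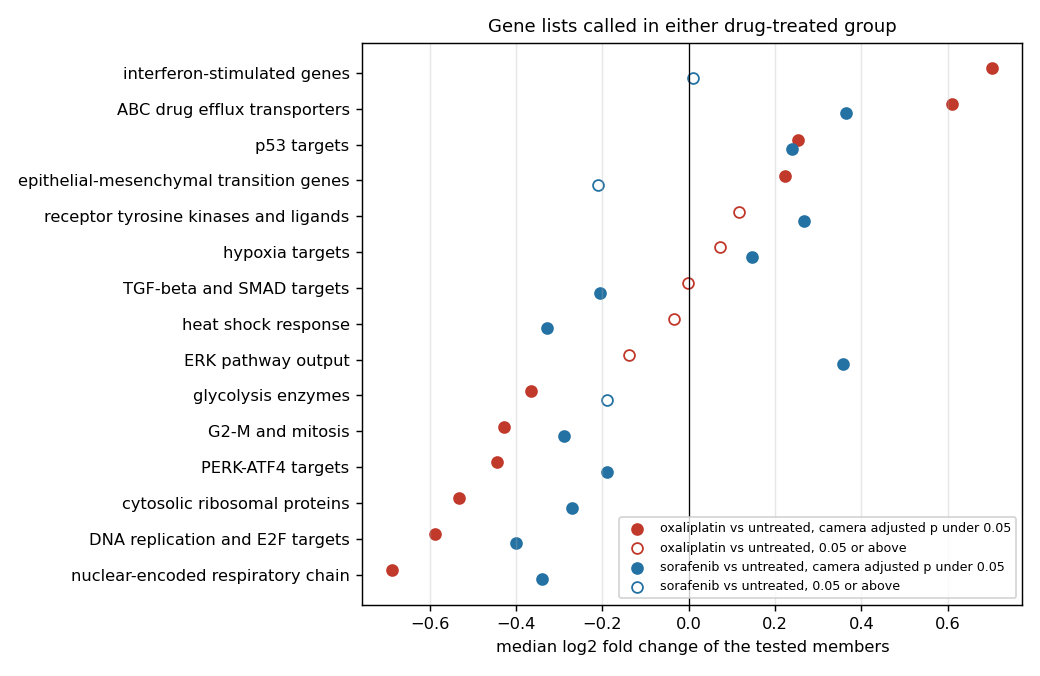
Points give the median log2 fold change of the tested members of 15 gene lists in oxaliplatin and in sorafenib against untreated libraries, filled where the camera test's adjusted p with the preset correlation was under 0.05. Replication and E2F targets lie at -0.59 and -0.40, and interferon-stimulated genes at 0.70 and 0.01.

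The third comparison sets the oxaliplatin libraries against the sorafenib libraries and so tests directly whether these 2 groups of libraries differ. With 1 library code per group, an effect of the drug cannot be told apart from one of the culture or the preparation. GFRA1, a co-receptor gene for a neurotrophic factor (ENSG00000151892, chr10:116056925-116273467), was at 48.1 ± 2.11 CPM in oxaliplatin and 2.86 ± 0.340 CPM in sorafenib (mean ± SD, n = 3 each), a log2 fold change of 4.07 ± 0.23 (SE, adjusted p = 2.33e-05). EGR1, an immediate early gene downstream of ERK (ENSG00000120738, chr5:138465479-138469303), was at 86.0 ± 16.9 and 6.64 ± 1.05 CPM (3.70 ± 0.21, adjusted p = 2.33e-05), and FN1 was higher in oxaliplatin by 3.64 ± 0.16 (adjusted p = 1.12e-05). DCLK1, a kinase gene linked to microtubules, and TAGLN, the gene of a smooth muscle protein, completed the 5 highest at 3.80 ± 0.42 and 3.77 ± 0.49 (adjusted p = 0.000798 and 0.00221). CA12 was lower in oxaliplatin at -3.89 ± 0.34, ETV4 at -3.82 ± 0.23, TMCC3 at -3.01 ± 0.17 and the membrane glycoprotein gene CDCP1 at -2.86 ± 0.20 (adjusted p = 0.00029, 3.16e-05, 2.33e-05 and 8.24e-05). The fifth lowest, ADGRF1 (-2.47 ± 0.55, adjusted p = 0.0272), had adjusted p-values of 0.101, 0.0943 and 0.0670 without oxaliplatin 1, 2 and 3 and of 0.0643, 0.0686 and 0.0717 without sorafenib 1, 2 and 3, in a range of 1.13e-05 to 0.101 over 17 alternatives.

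Between the drug groups 1659 genes were called, 840 higher and 819 lower in oxaliplatin, which is 10.3% of those tested, and 602 with a change of at least 2-fold, 374 higher and 228 lower. With scaling by library size only, 1072 were higher and 599 lower, and 446 and 172 with a change of at least 2-fold. Groups without overlap were found for 34.9% of tested genes, where chance gives 10%. The count was 572 and 723 without oxaliplatin 1 and 2, and 825, 956 and 787 without sorafenib 1, 2 and 3, and the 2-fold count was 337, 381 and 395 without oxaliplatin 1, oxaliplatin 2 and sorafenib 1.

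Interferon-stimulated genes were higher in oxaliplatin than in sorafenib, with 14 of 32 members higher and 0 lower (26 and 1 adjusted over the list alone). The median was 0.78 (adjusted p = 4.59e-15; adjusted p = 0.0256 with an estimated correlation). GBP1 was at 12.3 ± 0.689 against 1.23 ± 0.630 CPM (log2 fold change 3.31 ± 0.33, adjusted p = 0.000516). The antiviral genes IFIT1 and IFIT3 had 1.21 ± 0.17 and 1.12 ± 0.14 (adjusted p = 0.00347 and 0.00141). Genes of antigen presentation were higher, with 4 of 15 higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.46 (adjusted p = 0.00422; adjusted p = 0.213 with an estimated correlation). PSMB9, an immunoproteasome gene, had 2.03 ± 0.34 (adjusted p = 0.00628). The epithelial-mesenchymal transition list had 11 of 29 higher and 2 lower (13 and 3 adjusted over the list alone). The median was 0.42 (adjusted p = 3.13e-09; adjusted p = 0.0216 with an estimated correlation). THBS1 was at 771 ± 48.1 against 261 ± 24.3 CPM and TGFBI, an adhesion gene induced by TGF-beta, at 1381 ± 266 against 489 ± 33.4 CPM (adjusted p = 0.000178 and 0.000605). TGF-beta and SMAD targets had 8 of 27 higher and 1 lower (9 and 3 adjusted over the list alone). The median was 0.27 (adjusted p = 0.0204; adjusted p = 0.271 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.00641). The call ended without oxaliplatin 3 (adjusted p = 0.0650).

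ERK pathway output was lower in oxaliplatin than in sorafenib, with 15 of 31 members lower and 5 higher (18 and 5 adjusted over the list alone). The median was -0.58 (adjusted p = 1.38e-06; adjusted p = 0.0455 with an estimated correlation). The phosphatase genes DUSP5 and DUSP6 had -1.94 ± 0.14 and -1.26 ± 0.15, ETV5 -1.55 ± 0.15 and SPRY4 -1.56 ± 0.18 (adjusted p = 8.24e-05, 0.00118, 0.000352 and 0.000856), whereas EGR1 of the same list was higher. Targets of YAP and TEAD were lower, with 5 of 22 lower and 1 higher (9 and 3 adjusted over the list alone). The median was -0.20 (adjusted p = 0.00992; adjusted p = 0.499 with an estimated correlation). The ectonucleotidase gene NT5E had -1.15 ± 0.12 (adjusted p = 0.000592). PERK-ATF4 targets were lower, with 5 of 35 lower and 0 higher (6 and 0 adjusted over the list alone). The median was -0.25 (adjusted p = 0.00422; adjusted p = 0.595 with an estimated correlation and 0.110 with fry). SLC7A5 had -1.07 ± 0.14 and TRIB3 -1.05 ± 0.19 (adjusted p = 0.00202 and 0.0097). HSPA5 was at -0.63 ± 0.14 (adjusted p = 0.0215), with adjusted p-values of 0.0824 and 0.0626 without oxaliplatin 1 and 2, and of 0.0538, 0.0519 and 0.0717 without sorafenib 1, 2 and 3, in a range of 0.00174 to 0.0824 over 17 alternatives. The copper uptake gene SLC31A1 was lower in oxaliplatin, at -0.53 ± 0.09 (adjusted p = 0.00816). LMNB1 did not pass the test between the groups (82.2 ± 3.75 and 82.4 ± 7.79 CPM, adjusted p = 0.990), nor did CDKN1A (0.77 ± 0.26, adjusted p = 0.0925).

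Of all list calls in the 3 comparisons, those of interferon-stimulated genes, the epithelial-mesenchymal transition and ERK output between the drug groups were the 3 that held with an estimated correlation. Metabolic lists were called lower in oxaliplatin than in sorafenib. The respiratory chain list had 6 of 46 lower and 0 higher (14 and 0 adjusted over the list alone, median -0.36, adjusted p = 1.14e-06; adjusted p = 0.499 with an estimated correlation and 0.0502 with fry). The glycolysis list had 4 of 19 lower and 0 higher (5 and 0 adjusted over the list alone, median -0.31, adjusted p = 0.000338; adjusted p = 0.456 with an estimated correlation), with the hexokinase gene HK2 at 22.5 ± 1.08 against 44.8 ± 3.35 CPM (adjusted p = 0.00133). Replication and E2F targets had 6 of 47 lower and 1 higher (11 and 1 adjusted over the list alone, median -0.21, adjusted p = 0.0018; adjusted p = 0.512 with an estimated correlation). Ribosomal protein genes had 2 of 70 lower and 0 higher (0 and 0 adjusted over the list alone, median -0.25, adjusted p = 0.000462; adjusted p = 0.654 with an estimated correlation, the highest of 16 alternatives, the lowest being 5.06e-07). This call ended without sorafenib 1 (adjusted p = 0.125) and with fry (adjusted p = 0.169). Heat shock genes had 6 of 24 higher and 0 lower (7 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.0150; adjusted p = 0.319 with an estimated correlation, the highest of 16 alternatives, the lowest being 0.00225). This call ended without oxaliplatin 3 (adjusted p = 0.0577) and without sorafenib 2 (adjusted p = 0.0525). HSPB8 and HSP90AA1, chaperone genes of that list, were higher by 0.75 ± 0.11 and 0.57 ± 0.11 (adjusted p = 0.00411 and 0.0105).

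**Figure D4:**
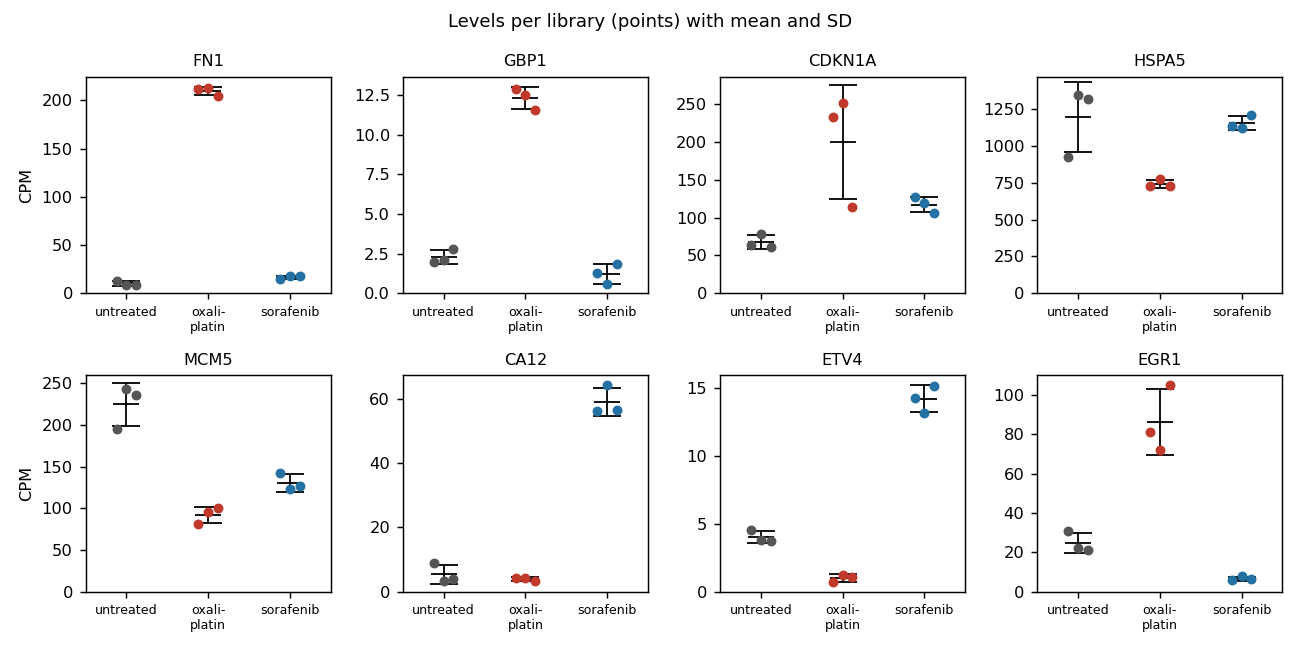
Points give CPM of FN1, GBP1, CDKN1A, HSPA5, MCM5, CA12, ETV4 and EGR1 in each library by group, with the mean and SD (n = 3). FN1 and GBP1 are highest in oxaliplatin (209 and 12.3 CPM on average) and CA12 and ETV4 in sorafenib (59.0 and 14.2 CPM).

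The last question is which changes the 2 drug groups share. LMNB1 fell to 82.2 ± 3.75 CPM in oxaliplatin and 82.4 ± 7.79 CPM in sorafenib from 137 ± 9.03 CPM, and ITGB3 rose to 17.3 ± 2.07 and 39.9 ± 6.89 CPM (mean ± SD, n = 3 each). MYBL2, TK1 and BAMBI were called lower and ABCA3 and SPRED3 higher in sorafenib, with oxaliplatin means of 160.4, 91.0, 9.58, 50.6 and 6.99 CPM against untreated means of 402, 207, 27.4, 33.1 and 2.24 CPM. In all, 290 genes were higher in both and 159 lower in both, 449 together. Independent lists of these sizes would share 73.9 and 49.4, but both comparisons use the same untreated libraries, so these values are not those expected without a shared change. These were 63.6% of the genes called higher and 49.8% of those called lower in sorafenib. Across the 16159 genes, which are not independent, the fold changes of both comparisons correlated with r = 0.580, and 20 simulated pairs of unchanged groups against the same controls gave 0.499. The signs agreed in 74.9% of genes against 66.6% in the simulation, in which edgeR called 0 genes in both groups. All libraries, the untreated ones included, were drawn there with no gene changed, so 0 calls were nearly fixed. Each gene was drawn independently, so trends across many genes of a library, such as those with GC content, were left out. The covariance was 0.266, against 0.0655 ± 0.00584 (SD) in the simulation, a difference of 0.201. The 3 untreated libraries are too few to split, so part of the excess may come from the shared controls. The count of 449 was 1202, 69 and 69 without untreated 1, 2 and 3, 174 and 215 without oxaliplatin 1 and 2, and 1225, 63 and 52 without sorafenib 1, 2 and 3. Of the oxaliplatin calls, 1197 also differed between the drug groups, and 3519 were neither called in sorafenib nor different between the drug groups.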

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

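The number of genes with the GC and length correction was chosen after the result was seen, and the other values below come from tests set beforehand. EGR1, an immediate early gene, rose in oxaliplatin and fell in sorafenib, from 24.7 ± 5.24 CPM in untreated libraries to 86.0 ± 16.9 and 6.64 ± 1.05 CPM (mean ± SD, n = 3 each, log2 fold changes 1.80 and -1.90, adjusted p = 0.00103 and 0.00191, higher in 3 of 3 and lower in 3 of 3 libraries). GFRA1 went the same ways (2.95 and -1.12, adjusted p = 0.000213 and 0.0250), and so did SDC2, the gene of the proteoglycan syndecan 2 (1.33 and -0.85), the endothelin gene EDN2 (0.57 and -1.51) and the integrin gene ITGB6 (0.53 and -0.72). ETV4 and ETV5, ETS factor genes downstream of ERK, fell in oxaliplatin and rose in sorafenib, as did the phosphatase gene DUSP5 (-0.97 and 0.97), the cytokine gene IL18 (-1.20 and 0.82), the atypical E2F gene E2F7 (-1.05 and 1.02) and the tight junction gene CLDN1 (-0.51 and 0.55). SDC2, EDN2, ITGB6, IL18, E2F7 and CLDN1 were chosen after their values were seen.

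What drew attention is that 50 genes were called in opposite directions in the 2 drug groups, 30 of them higher in oxaliplatin. The edgeR test between the drug groups called each of these 50 as well. DESeq2 gave 74 such genes, RLE factors 51, a filter on mean CPM 56 and the correction for GC content and length 72, while the fit with the replicate number as a block gave 18. Leaving out untreated 2 or untreated 3 gave 14 and 16, oxaliplatin 1 or 2 gave 28 and 31, and sorafenib 2 or 3 gave 16 and 13, while leaving out untreated 1, oxaliplatin 3 or sorafenib 1 gave 46, 47 and 47. The 50 genes stand beside 449 called in the same direction. Independent lists of the sizes called in each direction would share more than 50 genes in opposite directions, so the count is no excess over them. Both comparisons use the same untreated libraries, so independent lists do not give the number expected without a shared change. The genes were selected on the contrasts that they are counted in, so the direct test is not independent of the selection. A called rise and a called fall add up in that test, so its outcome was nearly fixed. No explanation was tested.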

How the results depend on the processing

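The correction for GC content and length and the omission of overlapping genes were chosen after the results were seen, and the other tests below were set beforehand. Over all alternatives, 1771 of 1872 results for gene lists stayed on their side of the threshold, 53 calls were lost, 48 were gained and 0 reversed. Of 4488 results for named genes, 3978 stayed, 435 calls were lost, 56 were gained, 19 uncalled values moved by more than 1 SE and 0 reversed. Of 185 counts, 129 stayed within 1.5 times the reported value. The causes of the changes were not tested unless given.

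For sorafenib against untreated, DESeq2 called 1805 genes, 523 of them with a 2-fold change, and 1137 genes in both drug groups, and 771 of the 775 calls were among its calls. With only the 6 libraries of the comparison fitted, 311 and 178 genes were called, with fewer libraries behind each dispersion. Requiring a 2-fold change in both left 131 shared genes, a stricter demand by construction, and the GC and length correction gave 681. With an estimated correlation, camera called 0 lists in oxaliplatin, 0 in sorafenib and 3 between the drugs, and fry called 22, 11 and 15. The call of PERK-ATF4 targets in sorafenib had an adjusted p of 0.0635 with the GC and length correction, within 0.000232 to 0.655 over its alternatives, and those of the genes P4HB and FGF2 in oxaliplatin had 0.0846 and 0.455. Scaling by library size only shifted the median log2 fold change in oxaliplatin to 0.131, from 0.016, so that 3395 genes were called higher and 1794 lower (1072 and 599 between the drugs), and no list call was lost. Without genes that overlap another on the same strand, 4479, 908 and 1545 genes were called in the 3 comparisons.

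Replicate numbers did not pair the libraries. Correlations of the libraries' deviations from their group means were -0.111 to 0.036 for the 9 pairs with the same number and -0.104 to 0.162 for the 18 others, so a block on the number spends degrees of freedom without a pairing to remove. The fit with that block called 184 genes in sorafenib, 138 with a 2-fold change, 809 between the drugs, 84 in both and 18 in opposite directions.

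Leaving out 1 library at a time gave 2913 to 5403 genes in oxaliplatin (without oxaliplatin 1 and without untreated 1), 113 to 1743 in sorafenib (without sorafenib 3 and without sorafenib 1), 572 to 1949 between the drugs (without oxaliplatin 1 and without untreated 1) and 52 to 1225 in both (without sorafenib 3 and without sorafenib 1). With a 2-fold change there were 90 to 630 in sorafenib (without sorafenib 3 and without untreated 1) and 337 to 728 between the drugs (without oxaliplatin 1 and without oxaliplatin 3). Between 9 and 12 lists were called in oxaliplatin, 10 and 12 in sorafenib, and 10 and 14 between the drugs. Counts in sorafenib thus rose without untreated 1 (1641 genes) or sorafenib 1 and fell without untreated 2 (149), untreated 3 (153), sorafenib 2 (139) or sorafenib 3. On simulated data, with 50 genes changed 2-fold among 15881 tested, 44% of these changes were called. The adjustment of p-values depends on the share of genes that change, and 31.7% of genes were called in oxaliplatin against untreated. The simulated share therefore cannot tell how many changes were missed with 3 libraries per group.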

Other observations

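The tests of renal and colorectal genes as lists, of the on-off genes and of GC content and length were chosen after the data had been looked at, as were the tests of mixed cells and of lost identity, while the bound on PAX8 and EPCAM was set before their levels were seen. Renal genes stood higher in oxaliplatin. Of 19 tested members of the renal list, edgeR called 10 higher and 2 lower in oxaliplatin, with a median log2 fold change of 0.78 (limma's camera test, unadjusted p = 1.04e-06; p = 0.0309 with an estimated correlation). It called 9 higher and 1 lower between oxaliplatin and sorafenib, with a median of 0.52 (limma's camera test, unadjusted p = 5.57e-10; p = 0.0157 with an estimated correlation). SIM1, a transcription factor gene of the developing kidney, rose from 7.85 to 58.7 CPM (2.90 ± 0.21), PKHD1, whose product lines renal tubules, from 3.39 to 26.8 CPM (2.99 ± 0.37), and the cadherin gene CDH6 from 8.30 to 33.6 CPM (2.02 ± 0.21, n = 3 each). PAX8 was at 0.06 in that comparison. In sorafenib 1 member was higher and 2 lower, with a median of 0.09 (limma's camera test, unadjusted p = 0.934). Of 8 tested colorectal genes, 1 was higher and 5 lower in oxaliplatin, 0 and 0 in sorafenib, and 0 and 1 between the drugs (limma's camera test, unadjusted p = 0.0266, 0.532 and 0.0225; p = 0.137, 0.628 and 0.141 with an estimated correlation). SIM1, PKHD1, ACSM2A, ACSM2B and VIM had been seen among the changed or abundant genes before the renal list was written, so its rise is not independent evidence of a direction.

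Several other fixed lists were not called in oxaliplatin. Of 38 Fanconi anaemia and homologous recombination genes 7 rose and 11 fell (10 and 14 adjusted over the list alone, camera adjusted p = 0.353), and of 31 NRF2 and glutathione genes 7 rose and 10 fell (7 and 11 adjusted over the list alone, adjusted p = 0.320). Of 25 ferroptosis regulators 4 rose and 11 fell (4 and 11 adjusted over the list alone, adjusted p = 0.0961), and of 29 cholesterol biosynthesis genes 1 rose and 6 fell (1 and 4 adjusted over the list alone, adjusted p = 0.0841).

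The identity of the libraries labelled HCT-15 is open, and the hypothesis is that they come from a renal cell line and not from the labelled colorectal line. A renal line would show PAX8 in every library and little EPCAM, and the lowest PAX8 value was 247 CPM, with a median EPCAM of 0.643 CPM. EPCAM belongs to the colorectal genes whose low level is to be explained, so its level cannot tell a renal source from another. Of 22 renal genes, 11 had a median of 10 CPM or more, while 3, CA9, NDUFA4L2 and EMX2, had one under 1 CPM. A minor share of renal cells among colorectal cells is argued against by EPCAM, at 1.38 CPM at most, and by CDH1 and CDX2, at 0 counts in all 9 libraries. Loss of colorectal identity during drug selection is argued against by the untreated libraries, where EPCAM was also at 1.38 CPM at most and CDH1 at 0 counts. VIL1 went the way of such a loss in untreated 2 and 3, at 6.91 and 7.27 CPM, against 0.107 CPM or lower in the drug libraries. In untreated 1 it was at 0.176 CPM. Of 8 tested colorectal genes, 5 were lower and 1 higher in oxaliplatin, and 0 were called in sorafenib. The titles carry the number 769, whose meaning the labels do not give, a renal line named 769-P is a candidate source that was not tested for lack of a genotype, and a PAX8-expressing line of another origin stays open. The liver marker FGB and the neural marker NEFL had medians of 102 and 126 CPM, and no test was made of which line would show both.

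Genes that are AT-rich and long tended to be higher in both drug groups, with Spearman correlations across genes between log2 fold change and GC content of -0.27 in oxaliplatin and -0.24 in sorafenib, and of 0.21 and 0.17 with length. Libraries of 1 group differed as well. Between a library's deviation from its group mean and GC content the correlation was -0.29, -0.46 and 0.55 in oxaliplatin 1 to 3, 0.41, -0.21 and -0.38 in sorafenib 1 to 3, and 0.03, 0.18 and -0.24 in untreated 1 to 3. With a correction per library for GC content and length, 91.0% of the 775 sorafenib calls kept their direction and call. In oxaliplatin 80.9% of the 5123 calls did, and 28 changed sign, which argues against this bias as the whole cause of the calls. The bias may still account for calls that ended, such as that of IPMK, whose log2 fold change went from 0.67 ± 0.16 to 0.00 ± 0.09. A biological cause of the trend was not tested.

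In 79 genes the libraries of 1 group differed at least 8-fold, with 0.5 CPM added to the lowest and a highest value of at least 20 CPM, and 6 of these genes were called. CLDN4 was 1 of the 79. Of 77 with an annotation, 50.6% had exons overlapping another gene on the same strand, against 16.7% of 790 matched genes (Fisher's exact test, one-sided, p = 1.33e-10), and with the overlapping genes added 69.2% of 39 fell under 3-fold. Adding an abundant partner lowers any range, and by a measure chosen after that result was seen the range of the sum was under 50% of the gene's own in 11 of 39, with a median ratio of 0.805, so reads moved between such genes may explain part of them and the rest stays open. RPS10-NUDT3 stood at 90.6, 13.2 and 177 CPM in untreated 1 to 3, with NUDT3 at 199.5, 183 and 45.1 CPM. Only untreated 3 had the first at its highest and the second at its lowest. From untreated 1 to untreated 2 both were lower, and their sum went from 290 to 196 CPM, which an exchange between these 2 does not give. With the correction for GC content and length, 89.9% of the 79 kept the 8-fold range. That correction is a smooth curve that shifts all genes of like GC content and length alike. It could hardly remove 8-fold differences of single genes, so this result cannot decide whether GC content and length play a part.

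The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many calls as the real split: 4582 genes in oxaliplatin against untreated, 311 in sorafenib against untreated and 1573 between the drugs, with 1, 5 and 3 as the highest of the others. Every other split has libraries of both groups on each side, so a difference between the groups adds to the spread within a side. Low counts in those splits are therefore no measure of chance, and no conclusion is drawn from them.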
